A study of Homo sapiens with 9 samples.

How the data were processed

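The series holds RNA-seq libraries of H358, a human non-small cell lung carcinoma cell line grown in RPMI medium with fetal bovine serum, from total RNA. The labels give 3 groups of 3 libraries: the parental line, a CRISPR knockout of SMARCA4, which encodes BRG1, and a CRISPR knockout of SMARCA2, which encodes BRM. BRG1 and BRM are the alternative ATPases of SWI/SNF chromatin remodelling complexes. The labels number the replicates but do not say whether they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Whether a knockout is a clone or a pool, and which sites the guides cut, is not given in the sources used here. The parental line is the only control named, so effects of editing and culture cannot be told apart from those of a lost gene. Below, BRG1 loss and BRM loss stand for the knockout groups.

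Each deposited file holds the estimated counts of 1 library, which Salmon made per transcript and did not normalize, per the file headers and the submitters' processing notes. The TPM values in the same files were made by the authors' Salmon run, per the file headers, and scale each library to the same total. The submitters' processing notes name Salmon, DESeq2 and the hg38 genome build. The versions, the transcript annotation, the library type, the strand setting and the bias settings are not given in the sources used here. The files list 203835 transcripts, of which 203746 were assigned to a gene of GENCODE release 29, 202888 of them with the same identifier and version. The 89 transcripts without a gene held at most 0.0193% of a library's reads and were left out. Coordinates are those of that annotation on hg38.

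Estimated counts were summed per gene, rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Of 58237 genes, filterByExpr with the groups kept 18205. TMM factors scaled the libraries, and 1 model with a mean per group was fitted to all 9 samples with glmQLFit (robust), which left 6 residual degrees of freedom and gave a common biological coefficient of variation of 0.253. The comparisons were BRG1 knockout against parental, BRM knockout against parental, and BRG1 knockout against BRM knockout, each with the quasi-likelihood F test (two-sided). Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, and every adjusted p of a gene in the text comes from this edgeR test. Log2 fold changes carry an approximate standard error (SE), computed as the absolute log2 fold change divided by the square root of its F statistic. It is not an error reported by the fit, and it is unreliable for genes with few or 0 reads in a group. Group means are TMM-scaled counts per 1e6 reads (CPM) with the standard deviation (SD) over 3 libraries.

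Gene lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 37 lists of a comparison. The test was repeated with the correlation estimated per list, and with fry, which tests whether the genes of a list move on balance 1 way without comparing them with other genes. The lists covered NRF2 targets, NRF2 regulators, SWI/SNF subunits, epithelial adhesion and identity, mesenchymal genes, alveolar and club cells, goblet and secretory airway cells, squamous and basal cells, neuroendocrine genes, the interferon response, MHC class I and class II presentation, NF-kB and inflammatory cytokines, and cholesterol and fatty acid synthesis. They also covered glycolysis and hypoxia, oxidative phosphorylation, the integrated stress response, p53 targets, cell division, MAPK output, AP-1 and immediate early genes, and YAP-TEAD, TGF-beta, Wnt and Notch targets. Further lists held extracellular matrix genes, adhesion molecules and cadherins, drug metabolism, Polycomb complexes, HOX genes, ribosomal proteins, mitochondrial transcripts, replication-dependent histones, and markers of fibroblasts, blood cells and endothelium. Symbols were matched to genes through current and older names, and 3 members had no gene in the annotation. The groups, lists, tests and the rule for named genes were chosen before the data were examined.

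Named genes follow this rule. In each comparison they are SMARCA4, SMARCA2, NFE2L2 and KEAP1, then the 8 protein-coding genes with the largest rise and the 8 with the largest fall. The latter needed an adjusted p under 0.05, a mean of at least 3 log2 CPM in the higher group, and 3 libraries of 1 group all above the 3 of the other. Last come up to 4 called members, with a mean of at least 1 log2 CPM, of each of the 8 lists with the smallest camera p, of the NRF2 targets and of the SWI/SNF subunits. Some genes that meet the rule are not reported here. Other genes named in the text were chosen after their values were seen. Against a group with 0 reads in all 3 libraries, a fold is a lower bound computed from 3 reads over the group. With 1 to 3 reads in a group, the ratio is given with its 95% counting interval. Such bounds and intervals cover counting error only, because the deposited values carry no molecular identifiers. Histone genes, AMY1C and other members of gene families share sequence with near-identical copies, and reads of an overlapping or antisense gene cannot be separated without a known strand setting, so values of such genes are uncertain.

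The same code was tested on simulated counts with 200 changed genes, 100 at a log2 size of 1 and 100 at 2. At these sizes edgeR recovered 38 and 93 in the simulated comparison of BRG1 knockout and parental over 17103 genes, 54 and 87 in that of BRM knockout and parental over 17127, and 51 and 88 in that of the 2 knockouts over 17239, with 8, 6 and 6 false calls. Alternatives tried were DESeq2 1.42.0, RLE size factors, no filter and a stricter filter on low counts, length-scaled counts from the TPM values, the replicate number as a block, limma voom, fits of only the 6 samples compared, a log2 threshold, and leaving out each library. Added after the data were seen were a correction of each library for GC content and length, the omission of parental replicate 1 with BRG1 knockout replicate 3, and the omission of BRG1 knockout replicates 1 and 2. Figures were drawn with matplotlib 3.10.9.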

Results

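Gene expression was measured by RNA-seq in H358, a human non-small cell lung carcinoma line with epithelial traits, in 3 groups of 3 libraries. The groups were the parental line, cells with a CRISPR knockout of SMARCA4 (BRG1), and cells with a CRISPR knockout of SMARCA2 (BRM). The parental libraries held 31969961, 37356292 and 40172192 estimated reads, the BRG1 knockout libraries 34676466, 39448251 and 36709911, and the BRM knockout libraries 37710368, 33720255 and 40679073. No pair of replicates agreed within sampling noise, with chi-square values per degree of freedom from 11.2 to 202 over the genes. The first principal component of log2 CPM carried 56.7% of the variance and placed the BRG1 knockout libraries at 115 to 144, against -89.2 to -33.4 for all others. On the second component, with 25.1%, the parental libraries lay between -97.5 and -58.5 and both knockouts between 10.3 and 70.7. Replicates within the BRG1 knockout differed: ribosomal protein genes took 9.98% and 10.6% of the reads in replicates 1 and 2 and 5.69% in replicate 3, against 4.85% to 5.68% in parental cells. Of 18205 genes tested, 11224 differed among the 3 groups in the edgeR quasi-likelihood test.

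The knocked-out genes were read first in each library. SMARCA4 (ENSG00000127616.18; hg38 chromosome 19, 10960825 to 11079426, plus strand) stood at 23.9, 21.2 and 23.6 CPM in the BRG1 knockout. It stood at 244, 216 and 212 CPM in parental cells and at 239.8, 245 and 249 CPM in the BRM knockout. It fell by 3.29 ± 0.14 on the log2 scale in the BRG1 knockout (SE, n = 3 per group; edgeR adjusted p = 4.1e-07), and its change of 0.13 ± 0.13 in the BRM knockout did not pass (adjusted p = 0.46). After the correction for GC content and length the latter change was -0.38 and passed (edgeR adjusted p = 0.013). SMARCA2 (ENSG00000080503.23; chromosome 9, 1980290 to 2193624, plus strand) stood at 10.3, 12.01 and 9.36 CPM in the BRM knockout, against 49.3, 58.0 and 55.5 CPM in parental cells. There it fell by 2.36 ± 0.23 (adjusted p = 1.1e-04). In the BRG1 knockout it was at 42.4, 32.02 and 61.3 CPM, a change of -0.26 ± 0.22 that did not pass in the edgeR test (adjusted p = 0.35). Without BRG1 knockout replicate 3 that change was -0.62 and passed (edgeR adjusted p = 0.012). Reads over an edited gene do not measure its protein.

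**Figure D1:**
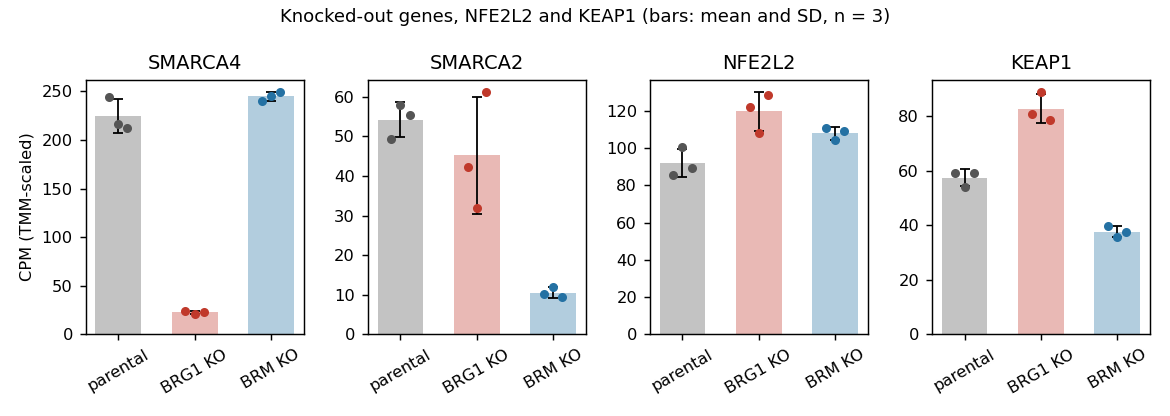
TMM-scaled CPM of SMARCA4, SMARCA2, NFE2L2 and KEAP1 in each library (points), with the mean (bar) and SD (error bar) of 3 libraries per group. SMARCA4 is lowest in all 3 BRG1 knockout libraries and SMARCA2 in all 3 BRM knockout libraries, while SMARCA2 spreads widely in the BRG1 knockout, with a mean of 45.2 ± 14.8 CPM.

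The comparison of BRG1 knockout with parental cells addresses what the loss of BRG1 does to expression in this line, NRF2 signalling included. NKX2-1, the transcription factor of lung epithelial identity, went from 80.8 ± 21.3 CPM (SD, n = 3) to 2 reads in the 3 knockout libraries together, against 8943 reads in parental cells, a ratio of 4334 with a 95% counting interval from 1199.7 to 35786. SPARC, a secreted matrix glycoprotein, rose from 82.6 ± 13.6 to 1792 ± 345 CPM (log2 4.44 ± 0.27, SE; edgeR adjusted p = 1.6e-06). In all, 3930 genes rose and 3984 fell of 18205 tested, 43.5% of them (edgeR quasi-likelihood test, adjusted p under 0.05). The counts were 3977 and 5002 when parental replicate 1 and BRG1 knockout replicate 3, which stood apart from their groups, were left out.

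Among the 8 largest rises by the naming rule, PCBP3, an RNA-binding protein, and CTNNA2, the neuronal alpha-catenin, had 0 parental reads and were at least 472-fold and 372-fold higher. CYTL1 and ZNF423, a zinc-finger transcription factor, had 1 parental read each. Their ratios were 2794, with a 95% counting interval from 501 to 110360.0, and 1056, with one from 189.6 to 41731. MN1, a transcriptional coregulator, rose from 0.174 ± 0.0650 to 104 ± 24.8 CPM, and COL8A2, a collagen chain, by 8.97 ± 0.58 on the log2 scale. SLC1A3, a glutamate transporter, and RFTN1, a lipid raft protein, rose by 9.76 ± 1.03 and 9.65 ± 0.87. On the other side, the tyrosine kinase SYK and the potassium channel KCNQ3 had 0 reads in the knockout and were at least 1113-fold and 361-fold lower. Single reads were left of GPR158, an orphan receptor, of F5, coagulation factor V, of TENM4, a teneurin, and of SOD3, extracellular superoxide dismutase. These 4 had 1606, 1282, 1202 and 1119 reads in parental cells, and the lower bounds of their counting intervals were ratios of 279, 223, 209 and 195. FGF13, a fibroblast growth factor homolog, went from 1580 to 4 reads. With NKX2-1, the edgeR adjusted p of these 16 genes lay between 4.1e-07 and 1.7e-04.

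Of the 30 measured genes of epithelial adhesion and identity, 28 fell and 2 did not pass, and all 30 fell when adjusted over the list alone. Their median log2 change was -3.50 (camera adjusted p = 7.4e-15; adjusted p = 0.446 with an estimated correlation). EHF, an epithelial ETS factor, fell by 7.65 ± 0.50, and GRHL2 and OVOL2, transcription factors that maintain epithelia, fell (log2 -4.73 ± 0.88 and -4.40 ± 0.71; SE, n = 3). The small GTPase RAB25 fell by 4.25 ± 0.88. The libraries of this group were unlike: the median of the list against the parental mean was -2.97 and -2.94 in BRG1 knockout replicates 1 and 2 and -6.14 in replicate 3. Secretory airway genes fell in 12 of 15 measured members and 3 did not pass, with 12 falls adjusted over the list alone. Their median was -4.50, or -3.69 with genes at 0 reads set to their bound (camera adjusted p = 5.9e-06; adjusted p = 0.446 with an estimated correlation). The gel-forming mucin MUC5B fell by 5.90 ± 0.39, the membrane mucin MUC4 fell by 5.84 ± 0.87, the disulfide isomerase AGR2 fell by 5.45 ± 0.85, and the adhesion molecule CEACAM6 fell by 5.44 ± 0.63. Alveolar and club cell genes fell in 8 of 15 members, rose in 1 and did not pass in 6, with the same counts adjusted over the list alone. The median was -0.73 (camera adjusted p = 0.0012; adjusted p = 0.446 with an estimated correlation), and -0.48 without parental replicate 1. FOXA1 and FOXA2, pioneer factors of endoderm, fell (log2 -4.67 ± 0.31 and -2.09 ± 0.26), and HOPX, a homeodomain protein of alveolar cells, fell by 4.01 ± 0.82.

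Mesenchymal genes rose in 17 of 22 measured members, fell in 1 and did not pass in 4, with the same counts adjusted over the list alone. The median was 1.61 (camera adjusted p = 4.7e-07; adjusted p = 0.231 with an estimated correlation). Besides SPARC, the gelatinase MMP2 rose by 6.21 ± 0.50 and the receptor tyrosine kinase AXL by 2.92 ± 0.31. Fibroblast markers rose in 5 of 8 members and 3 did not pass, with 5 rises adjusted over the list alone and a median of 2.65 (camera adjusted p = 3.2e-04; adjusted p = 0.249 with an estimated correlation). COL3A1, a fibrillar collagen, rose by 8.62 ± 1.05, with 84.5, 109 and 739 CPM in the 3 knockout libraries against 0.802 ± 0.466 in parental cells. The receptor PDGFRB rose by 6.35 ± 0.47 and COL1A1 by 3.12 ± 0.25, while COL1A2, the partner chain of COL1A1 in type I collagen, changed by -0.45 ± 0.53 and did not pass. Matrix genes rose in 20 of 44 members and fell in 8, and 16 did not pass (median 0.69; 21 higher and 9 lower adjusted over the list alone). The camera adjusted p was 0.0074 (adjusted p = 0.249 with an estimated correlation), and the median was 0.44 without BRG1 knockout replicate 3. TGF-beta targets rose in 10 of 18, fell in 2 and did not pass in 6, the same adjusted over the list alone (median 0.71; camera adjusted p = 0.0019; adjusted p = 0.231 with an estimated correlation). Targets of YAP and TEAD rose in 13 of 26, fell in 4 and did not pass in 9, or 14 and 4 adjusted over the list alone. Their median was 0.99 (camera adjusted p = 0.0024; adjusted p = 0.446 with an estimated correlation), and 0.57 without BRG1 knockout replicate 3.

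Interferon-stimulated genes fell in 28 of 42 measured members, rose in 5 and did not pass in 9, or 30 and 6 adjusted over the list alone. Their median was -1.42 (camera adjusted p = 3.2e-06; adjusted p = 0.72 with an estimated correlation). The antiviral genes CMPK2, RSAD2, OAS3 and DDX60 fell (log2 -5.25 ± 0.58, -4.65 ± 0.80, -4.44 ± 0.41 and -3.63 ± 0.31). MAPK output genes fell in 14 of 25, rose in 3 and did not pass in 8, or 15 and 4 adjusted over the list alone (median -0.88; camera adjusted p = 0.0024; adjusted p = 0.344 with an estimated correlation). Targets of the integrated stress response rose in 18 of 34, fell in 2 and did not pass in 14, or 19 and 2 adjusted over the list alone. With a median of 0.68, the camera adjusted p was 3.2e-04 (adjusted p = 0.72 with an estimated correlation). CHAC1, a glutathione-degrading enzyme, rose by 2.57 ± 0.27, the mTOR inhibitor DDIT4 by 2.31 ± 0.21, the serine synthesis enzyme PSAT1 by 1.61 ± 0.32 and HERPUD1, of endoplasmic reticulum protein disposal, by 1.59 ± 0.18. Ribosomal protein genes rose in 39 of 50 and 11 did not pass, with 43 rises adjusted over the list alone and a median of 0.84 (camera adjusted p = 3.2e-06; adjusted p = 0.887 with an estimated correlation). RPL13A, RPL10, RPL9 and RPL31 rose by 1.26 ± 0.22, 1.23 ± 0.17, 1.21 ± 0.24 and 1.17 ± 0.26. Cell division genes fell in 15 of 49 and 34 did not pass, with 11 falls adjusted over the list alone (median -1.04; camera adjusted p = 0.002; adjusted p = 0.887 with an estimated correlation). With BRG1 knockout replicates 1 and 2 left out, which left replicate 3 alone with the spread of the other groups, the ribosomal and cell division medians were 0.24 and -0.70 and neither list passed (camera adjusted p = 0.24 and 0.23).

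NRF2, the oxidative stress transcription factor encoded by NFE2L2, and KEAP1, which targets NRF2 for degradation, both rose at the RNA level. NFE2L2 (ENSG00000116044.15; chromosome 2, 177227595 to 177392697, minus strand) went from 92.0 ± 7.54 to 119.8 ± 10.4 CPM (log2 0.38 ± 0.13; edgeR adjusted p = 0.036). Its call was lost without any 1 of parental replicates 1 to 3, BRG1 knockout replicates 1 and 3 or BRM knockout replicates 1 and 3, with changes from 0.26 to 0.45 (edgeR adjusted p from 0.05 to 0.17). KEAP1 (ENSG00000079999.13; chromosome 19, 10486120 to 10503741, minus strand) went from 57.4 ± 3.01 to 82.7 ± 5.45 CPM (log2 0.53 ± 0.13; edgeR adjusted p = 0.0061). It lies near the edited SMARCA4, and a local effect of the editing on it was not tested. Of 37 measured NRF2 targets, 9 rose, 11 fell and 17 did not pass, or 10 and 11 adjusted over the list alone. The list did not pass as a whole, with a median of 0.10 and a mean of -0.09, which differ in sign (camera adjusted p = 0.98), and the median ran from -0.09 to 0.31 with 1 library left out. The glutathione peroxidase GPX2 fell by 4.83 ± 0.56 and GCLM, of glutathione synthesis, fell by 1.67 ± 0.21, whereas the ferritin light chain FTL and the heme oxygenase HMOX1 rose by 1.98 ± 0.24 and 1.91 ± 0.33. NRF2 regulators rose in 3 of 14, fell in 3 and did not pass in 8 (median 0.07; camera adjusted p = 0.86). Among 27 SWI/SNF subunits, with the edited SMARCA4 counted among the falls, 6 rose, 5 fell and 16 did not pass (median -0.08, mean 0.10, of opposite sign; camera adjusted p = 0.86). The subunit SMARCD3 rose by 4.25 ± 0.43. BCL7A fell by 1.03 ± 0.32, a call lost without parental replicate 1 or 3 (-0.88 and -1.06; edgeR adjusted p = 0.075 and 0.053). DPF1 rose by 0.97 ± 0.33, a call lost without any 1 parental library or BRG1 knockout replicate 2 (changes from 0.56 to 1.06; edgeR adjusted p from 0.067 to 0.2).

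**Figure D2:**
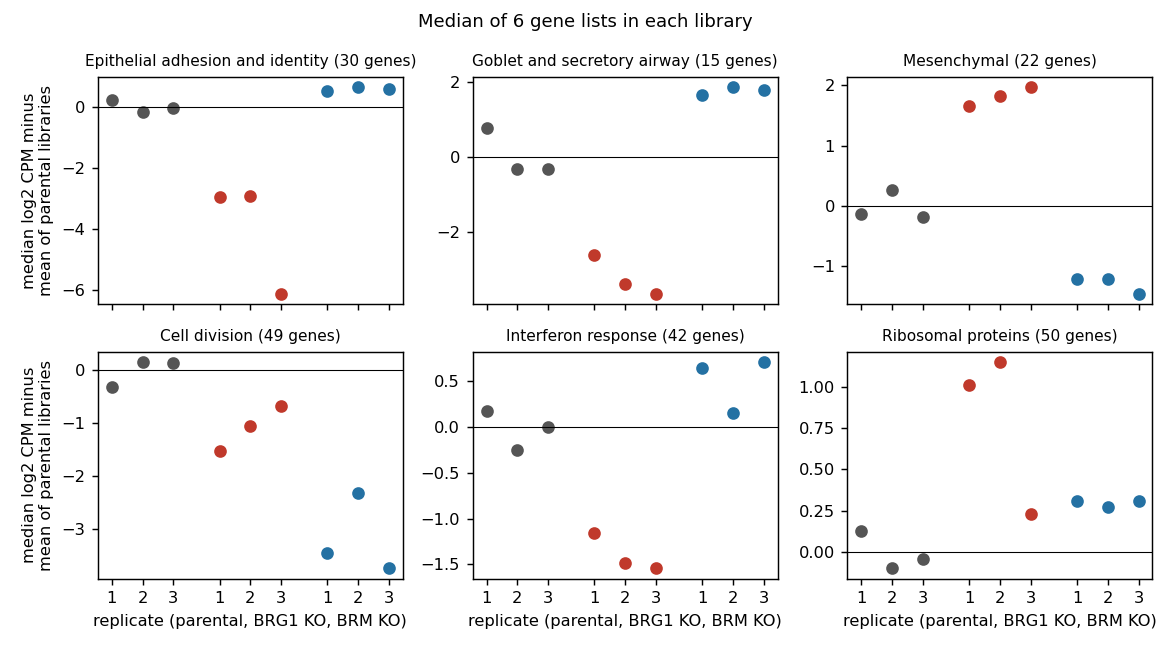
Median over the genes of 6 lists of log2 CPM minus the mean of the parental libraries (vertical axis, log2 units), 1 point per library, by group and replicate (horizontal axis). Epithelial genes lie at -6.14 in BRG1 knockout replicate 3 and at -2.97 and -2.94 in replicates 1 and 2, and ribosomal protein genes at 0.23 in replicate 3 and 1.01 and 1.15 in the others.

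The comparison of BRM knockout with parental cells asks the same of the other ATPase. MKI67, the proliferation marker, went from 319.9 ± 88.7 to 24.3 ± 16.2 CPM (SD, n = 3; log2 -3.72 ± 0.62, SE; edgeR adjusted p = 0.0017). SPARC went from 82.6 ± 13.6 to 1.97 ± 0.679 CPM and the mucin MUC5B from 53.2 ± 28.8 to 627 ± 76.8 CPM. In all, 3814 genes rose and 2991 fell, 37.4% of those tested (edgeR quasi-likelihood test). Without parental replicate 2 or 3 the genes that rose numbered 2457 and 2469, and with parental replicate 1 and BRG1 knockout replicate 3 left out the counts were 4282 and 4250. The excess of rises depended on the processing. In a fit of only the 6 samples 4137 rose and 4252 fell, and after the correction for GC content and length 3653 and 3945. With limma voom the counts were 4040 and 3118, and with the stricter filter 3508 and 2597.

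By the naming rule, the largest rises were of the transcription factor MAF (7.15 ± 0.51), FSTL4 (6.21 ± 0.40), AMY1C (5.93 ± 1.20), the serine protease TMPRSS2 (5.41 ± 0.85), MUC4 (5.28 ± 0.54), the cadherin CDH6 (5.20 ± 0.76), the adhesion receptor ADGRF5 (5.08 ± 1.10) and OLFM2 (4.84 ± 0.34). AMY1C, a salivary amylase, has near-identical copies that reads cannot separate. The largest falls were led by SOD3, with 1 read in the knockout against 1119, a ratio of 1091 with a 95% counting interval from 196 to 43100.0. The calcium-binding CALB2 went from 1818 to 7 reads and GPR158 from 1606 to 8. The semaphorin SEMA5A fell by 6.52 ± 0.54, the interleukin receptor IL4R fell by 6.05 ± 0.40, SPARC fell by 5.39 ± 0.29, the peptidase TRHDE fell by 5.28 ± 0.53 and the glycosyltransferase B3GALT5 fell by 5.13 ± 0.53. The edgeR adjusted p of these 16 genes lay between 1.2e-05 and 0.006.

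All 49 measured cell division genes fell, also adjusted over the list alone, with a median of -2.86 (camera adjusted p = 3.5e-32; adjusted p = 0.433 with an estimated correlation). The replication factor MCM10 fell by 3.82 ± 0.44, the transcription factor FOXM1 fell by 3.64 ± 0.45 and the mitotic kinase PLK1 fell by 3.58 ± 0.58. Replication-dependent histone genes, whose mRNAs mostly lack poly(A) tails, fell in 13 of 23, rose in 1 and did not pass in 9, the same adjusted over the list alone. Their median was -1.26 (camera adjusted p = 9.6e-05; adjusted p = 0.543 with an estimated correlation), and H2BC11, H2AC11, H2BC4 and H4C9 fell (log2 -4.39 ± 0.38, -2.29 ± 0.30, -1.83 ± 0.27 and -1.51 ± 0.31). Reads on rRNA genes, mitochondrial for the most part, made up 0.154 to 0.220% of the parental libraries, 0.357 to 0.492% of the BRG1 knockout and 0.437 to 0.651% of the BRM knockout libraries, and a part of library preparation in the histone change was not tested. Mesenchymal genes fell in 13 of 22, rose in 1 and did not pass in 8, the same adjusted over the list alone (median -1.42; camera adjusted p = 2.9e-07; adjusted p = 0.433 with an estimated correlation). AXL fell by 4.31 ± 0.35, N-cadherin, CDH2, fell by 2.79 ± 0.27, and ZEB2, a repressor of epithelial genes, fell by 2.69 ± 0.41. Epithelial genes rose in 5 of 30 and fell in 1, and 24 did not pass, with 3 rises adjusted over the list alone (median 0.51; camera adjusted p = 0.28).

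Secretory airway genes rose in 7 of 15, fell in 1 and did not pass in 7, the same adjusted over the list alone (median 1.67; camera adjusted p = 0.023; adjusted p = 0.787 with an estimated correlation). MUC5B and MUC16 rose by 3.56 ± 0.33 and 3.16 ± 0.39, and the adhesion molecule CEACAM5 by 3.19 ± 0.77, or 4.90 without parental replicate 1. Integrated stress response targets rose in 21 of 34 and 13 did not pass, the same adjusted over the list alone (median 0.83; camera adjusted p = 3.7e-05; adjusted p = 0.697 with an estimated correlation). The stress factor ATF3 rose by 2.10 ± 0.30, HERPUD1 by 1.87 ± 0.18, CHAC1 by 1.85 ± 0.26 and the glycine transporter SLC6A9 by 1.48 ± 0.31. Notch targets rose in 6 of 14 and 8 did not pass, or 10 higher and 1 lower adjusted over the list alone. Their median was 1.03 (camera adjusted p = 0.023; adjusted p = 0.632 with an estimated correlation), and 0.74 with no call after the correction for GC content and length (camera adjusted p = 0.069). LFNG, which modifies Notch receptors, rose by 2.23 ± 0.33, and the Notch-induced repressors HEYL and HES1 by 1.81 ± 0.31 and 1.10 ± 0.15. NOTCH3 rose by 1.66 ± 0.42, a call lost without parental replicate 3 (1.48; edgeR adjusted p = 0.054). Listed p53 targets rose in 11 of 24, fell in 5 and did not pass in 8, or 11 and 6 adjusted over the list alone (median 0.48; camera adjusted p = 0.033; adjusted p = 0.577 with an estimated correlation). The list lost its call in the stricter filter, with limma voom and with BRG1 knockout replicates 1 and 2 left out, at medians of 0.48, 0.49 and 0.38 (camera adjusted p = 0.062, 0.076 and 0.051). The stress protein TP53INP1, the cytokine GDF15, the cell cycle inhibitor CDKN1A and the apoptosis inducer BBC3 rose by 3.59 ± 0.29, 3.32 ± 0.76, 2.70 ± 0.37 and 2.64 ± 0.38.

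NFE2L2 was at 108 ± 3.45 CPM, a change of 0.23 ± 0.13 that did not pass (edgeR adjusted p = 0.19), and KEAP1 fell from 57.4 ± 3.01 to 37.6 ± 2.00 CPM (log2 -0.61 ± 0.13; edgeR adjusted p = 0.0036). Of 37 NRF2 targets, 12 rose, 4 fell and 21 did not pass, the same adjusted over the list alone, and the list did not pass (median 0.34, or 0.24 to 0.51 with 1 library left out; camera adjusted p = 0.18). The exporter ABCC3 rose by 1.88 ± 0.23 and GPX2 by 1.80 ± 0.42. OSGIN1 rose by 1.501 ± 0.42, a call lost without parental replicate 2 or 3 or BRM knockout replicate 2 (1.32, 1.35 and 1.16; edgeR adjusted p = 0.076, 0.075 and 0.065). NRF2 regulators rose in 4 of 14 and fell in 2 (median 0.05; camera adjusted p = 0.86). SWI/SNF subunits, with the edited SMARCA2 counted among the falls, rose in 3 of 27, fell in 6 and did not pass in 18 (median -0.11; camera adjusted p = 0.22). SMARCD3 rose by 3.23 ± 0.42 and ACTL6A fell by 0.99 ± 0.15. BCL7A rose by 1.25 ± 0.32, a call lost without parental replicate 2 or BRM knockout replicate 1 (1.13 and 1.05; edgeR adjusted p = 0.052 and 0.054).

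**Figure D3:**
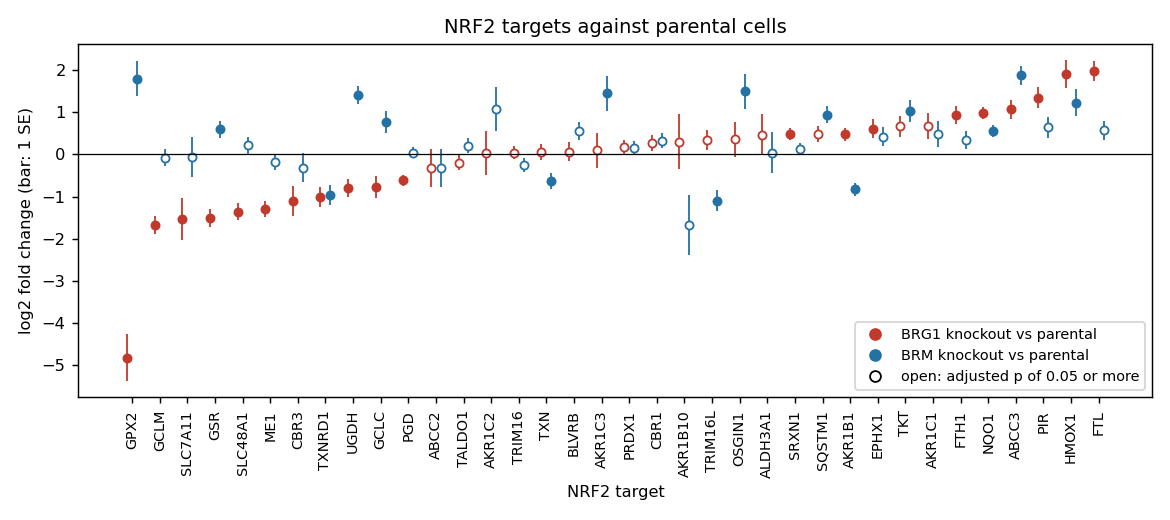
Log2 fold change against parental cells (vertical axis) of 36 of the 37 measured NRF2 targets (horizontal axis) in the BRG1 knockout (red) and the BRM knockout (blue), with 1 SE as bars and open points for an adjusted p of 0.05 or more. Targets go both ways in the BRG1 knockout, from GPX2 at -4.83 to FTL at 1.98, and GPX2 moves in opposite directions in the 2 knockouts.

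**Figure D4:**
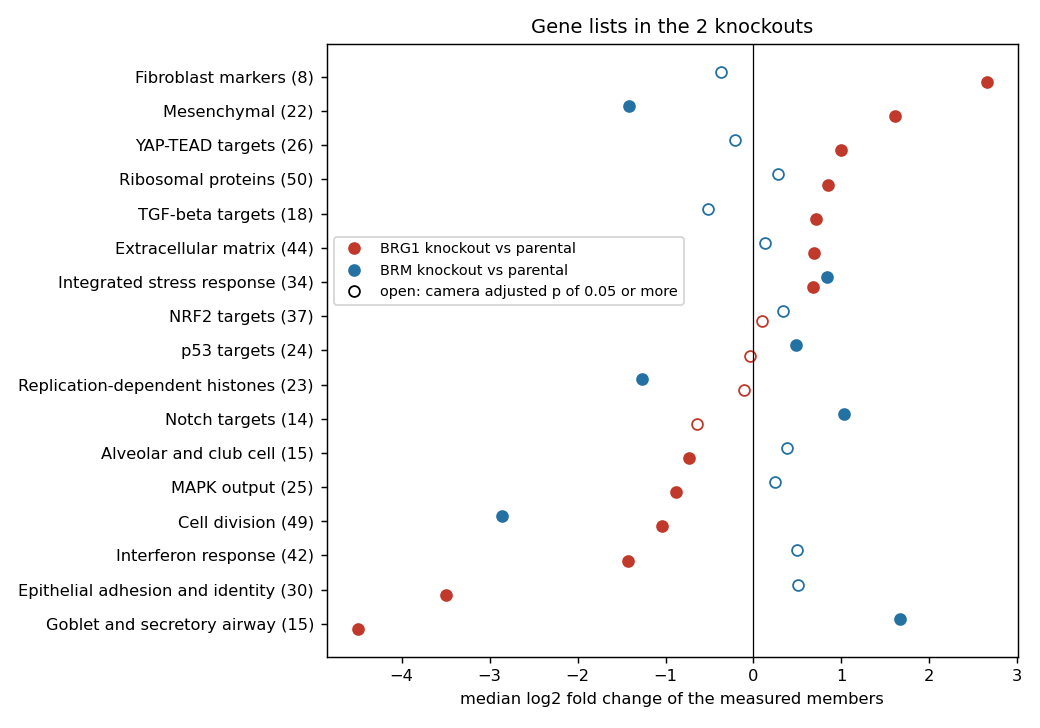
Median log2 fold change of the measured members (horizontal axis) of 17 gene lists (vertical axis, number measured in brackets) in the BRG1 knockout (red) and the BRM knockout (blue) against parental cells, with open points where the camera adjusted p is 0.05 or more. The secretory airway list lies at -4.50 and 1.67 and the mesenchymal list at 1.61 and -1.42, while the integrated stress response lies at 0.68 and 0.83.

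The direct comparison of BRG1 knockout with BRM knockout asks where the losses of the 2 ATPases differ. SPARC stood at 1792 ± 345 CPM in the BRG1 knockout and 1.97 ± 0.679 CPM in the BRM knockout (SD, n = 3; log2 9.83 ± 0.34, SE; edgeR adjusted p = 9.9e-08). MUC5B stood at 0.889 ± 0.0651 against 627 ± 76.8 CPM (log2 -9.46 ± 0.44; edgeR adjusted p = 2.7e-07). In all, 3925 genes were higher and 4327 lower in the BRG1 knockout (edgeR quasi-likelihood test), against 5433 and 3886 after the correction for GC content and length, which moved the share of higher calls from 47.6% to 58.3%.

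Of the largest differences by the naming rule, the metalloprotease ADAMTS9, CYTL1, the chemerin receptor CMKLR1, ZNF423 and the teneurin TENM2 had 0 reads in the BRM knockout. They were at least 2335-fold, 908-fold, 375-fold, 343-fold and 309-fold higher in the BRG1 knockout. FAM171A1 and the methyltransferase NNMT had 1 read each, for ratios with 95% counting intervals from 818 to 180100.0 and from 393 to 86515, and MN1 was higher by 10.42 ± 0.47. SYK and KCNQ3 had 0 reads in the BRG1 knockout and were at least 2432-fold and 1714-fold lower there. NKX2-1 had 2 reads and F5 1, for ratios with intervals from 3622 to 108050.0 and from 790.1 to 173870.0. MUC4, the glycosyltransferase B3GNT6, MCTP2 and the lung gene SFTA3 differed by -11.12 ± 0.81, -9.93 ± 0.88, -9.92 ± 0.64 and -9.76 ± 0.61. The edgeR adjusted p of these 16 genes lay between 9.9e-08 and 2.7e-04.

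All 30 measured epithelial genes were lower in the BRG1 knockout, also adjusted over the list alone, with a median of -4.29 (camera adjusted p = 1.5e-15; adjusted p = 0.403 with an estimated correlation). EHF, GRHL1 and the claudin CLDN3 differed by -6.59 ± 0.49, -6.17 ± 0.54 and -6.00 ± 0.75. Mesenchymal genes were higher in 15 of 22, lower in 1 and did not pass in 6, the same adjusted over the list alone (median 3.47; camera adjusted p = 1.5e-15; adjusted p = 0.0512 with an estimated correlation). MMP2, AXL and ZEB1, a repressor of epithelial genes, differed by 7.95 ± 0.56, 7.23 ± 0.39 and 5.17 ± 0.47. Cell division genes were higher in 43 of 49 and 6 did not pass, with 47 higher adjusted over the list alone (median 1.86; camera adjusted p = 3.2e-10; adjusted p = 0.429 with an estimated correlation). The thymidylate synthase TYMS, the transcription factor MYBL2, MCM10 and the kinetochore protein CENPF differed by 3.98 ± 0.43, 3.12 ± 0.47, 2.71 ± 0.42 and 2.55 ± 0.62. Interferon genes were lower in 30 of 42, higher in 2 and did not pass in 10, or 31 and 2 adjusted over the list alone (median -1.63; camera adjusted p = 1.8e-09; adjusted p = 0.41 with an estimated correlation). OAS1, MX2, MX1 and RSAD2 differed by -5.58 ± 0.61, -5.21 ± 0.63, -5.00 ± 0.58 and -4.87 ± 0.80. Secretory airway genes were lower in 12 of 15, higher in 1 and did not pass in 2, the same adjusted over the list alone. Their median was -7.11, or -6.65 with genes at 0 reads set to their bound (camera adjusted p = 9.5e-08; adjusted p = 0.318 with an estimated correlation), with CEACAM5 and MUC16 at -8.19 ± 1.13 and -7.66 ± 0.49.

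Alveolar and club cell genes were lower in 9 of 15, higher in 2 and did not pass in 4, the same adjusted over the list alone (median -1.75; camera adjusted p = 2.6e-05; adjusted p = 0.286 with an estimated correlation). HOPX, FOXA1 and the surfactant lipid transporter ABCA3 differed by -6.34 ± 0.86, -5.09 ± 0.31 and -3.53 ± 0.26. TGF-beta targets were higher in 11 of 18, lower in 1 and did not pass in 6, the same adjusted over the list alone (median 0.95; camera adjusted p = 2.6e-05; adjusted p = 0.0512 with an estimated correlation). BMP4, TGFBI and ID3 differed by 3.88 ± 0.19, 3.30 ± 0.26 and 3.09 ± 0.45. Targets of YAP and TEAD were higher in 13 of 26, lower in 3 and did not pass in 10, or 13 and 4 adjusted over the list alone (median 0.67; camera adjusted p = 3.2e-05; adjusted p = 0.286 with an estimated correlation). CCN2, IGFBP3 and TGFB2 differed by 5.68 ± 0.32, 4.71 ± 0.26 and 3.64 ± 0.26. Fibroblast markers had a median of 2.86 (5 of 8 higher, 1 lower, 2 not passing, the same adjusted over the list alone; camera adjusted p = 6.8e-04; adjusted p = 0.286 with an estimated correlation), and 1.74 or 1.77 without BRG1 knockout replicate 1 or 2. MAPK output genes had one of -0.98 (3 of 25 higher, 16 lower, 6 not passing, the same adjusted over the list alone; camera adjusted p = 8.5e-04; adjusted p = 0.279 with an estimated correlation). Notch targets lay at -1.59 (1 of 14 higher, 10 lower, 3 not passing, or 1 and 11 adjusted over the list alone; camera adjusted p = 0.0023; adjusted p = 0.403 with an estimated correlation). Histone genes lay at 1.19 (11 of 23 higher, 12 not passing, the same adjusted over the list alone; camera adjusted p = 0.0034; adjusted p = 0.41 with an estimated correlation).

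Ribosomal protein genes were higher in 21 of 50 and 29 did not pass, the same adjusted over the list alone, with a median of 0.54 (camera adjusted p = 0.0023; adjusted p = 0.906 with an estimated correlation). Without BRG1 knockout replicate 2 the median was 0.37 with no call, and without replicates 1 and 2 it was 0.03 (camera adjusted p = 0.056 and 0.89). Squamous and basal genes were lower in 9 of 14, higher in 3 and did not pass in 2, or 10 and 4 adjusted over the list alone, with a median of -1.85 and a mean of -0.69 (camera adjusted p = 0.0054; adjusted p = 0.41 with an estimated correlation). That list lost its call without BRG1 knockout replicate 3 (-1.46; camera adjusted p = 0.15). KEAP1 was higher in the BRG1 knockout by 1.14 ± 0.13 (edgeR adjusted p = 4.6e-05), and NFE2L2, at 0.15 ± 0.13, did not pass (edgeR adjusted p = 0.38). NRF2 targets were higher in 8 of 37, lower in 13 and did not pass in 16, the same adjusted over the list alone, and the list did not pass (median -0.37, or -0.39 to -0.16 with 1 library left out; camera adjusted p = 0.33). GPX2, UGDH, which makes UDP-glucuronate, and the glutathione reductase GSR differed by -6.63 ± 0.58, -2.21 ± 0.22 and -2.11 ± 0.21. Of 27 SWI/SNF subunits, the edited SMARCA4 and SMARCA2 included, 9 were higher and 5 lower (median 0.20; camera adjusted p = 0.48), with BCL7A at -2.28 ± 0.33 and DPF1 at 1.78 ± 0.34.

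Both knockouts were compared with the same parental libraries. They shared 2787 genes called in the same direction, 1600 higher and 1187 lower, where independent lists of these sizes would share 823 and 655. The shared count was 1651 without parental replicate 2 and 1671 without parental replicate 3. In opposite directions went 954 genes, 282 of them higher with BRG1 loss and 672 higher with BRM loss, where independent lists would share 646 and 835. Across genes, which are not independent replicates, the log2 fold changes of the knockouts had Pearson and Spearman correlations of 0.239 and 0.288. In 20 simulations of unchanged groups the mean Pearson correlation was 0.498. Shared controls alone give a value near that where no gene changes, so it is not a chance level for these knockouts. The covariance of the fold changes was 0.514 against 0.0729 in the simulations, a difference of 0.441. The simulations held 0 genes called in the same direction. With no gene changed hardly any call was likely there, so this sets no bound on the part of the shared controls. With 3 parental libraries no split into parts of at least 2 was possible, so part of the shared calls may come from the shared controls. The labels name no control cells that went through editing. Effects of editing or culture that both knockouts may share therefore cannot be told apart from effects of the 2 losses.

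Along the chromosomes, 11535 protein-coding genes were read in 230 windows of about 50 neighbours. The median change of a window lay at least 0.5 from that of all genes in 13 windows of the BRG1 knockout, 8 lower and 5 higher, and in 11 of the BRM knockout, 6 lower and 5 higher. In 1000 random gene orders the means were 0.03 and 0.01 windows and the highest count was 1. On chromosome 8, 3 windows between 56 and 144 Mb, with 153 genes, lay between -0.70 and -0.82 in the BRG1 knockout, while a window between them was not shifted. Of these 153 genes, 93 fell and 10 rose (edgeR quasi-likelihood test). On chromosome 16, 3 windows from 11 to 47 Mb, with 151 genes, lay between -0.57 and -0.63 in the BRM knockout, and 79 of these genes fell and 7 rose. In the BRM knockout 2 windows further along chromosome 16 shifted the other way, at 0.54 and 0.67, and 3 windows of chromosome 12 lay between -0.54 and -0.65. In the BRG1 knockout 2 windows of chromosome 17 lay at 0.75 and 0.52, and chromosome 11 held 2 lower windows, at -0.53 and -0.56, and 1 higher, at 0.59.

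**Figure D5:**
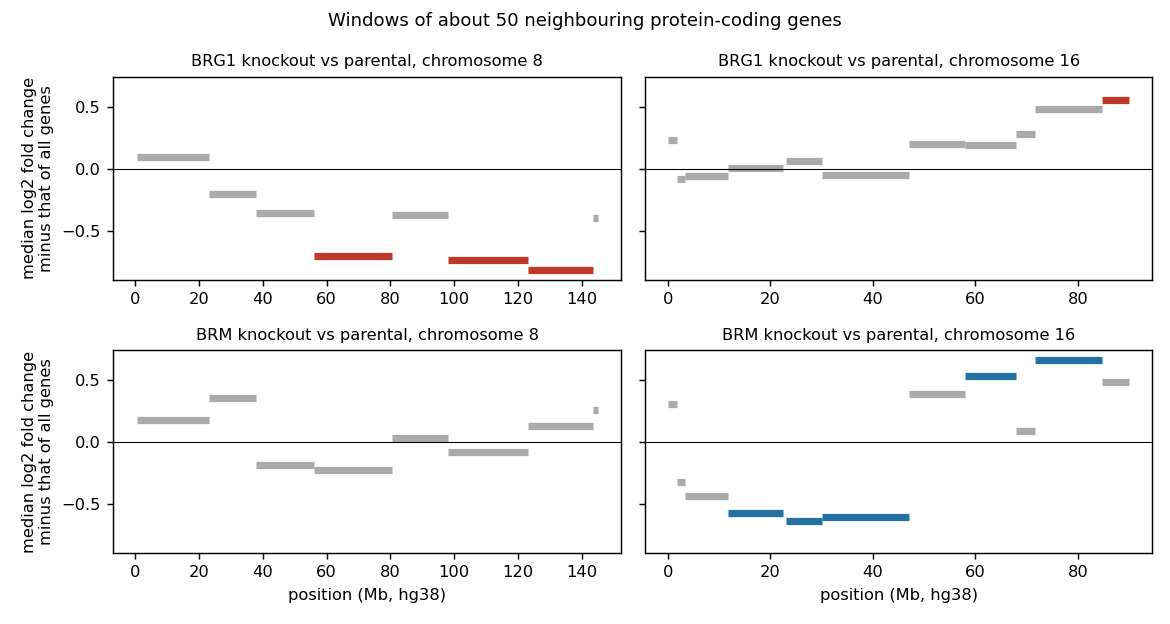
Median log2 fold change minus that of all genes (vertical axis) in windows of about 50 genes by position in Mb (horizontal axis) on chromosomes 8 and 16, in the BRG1 knockout and the BRM knockout against parental cells, coloured where the distance is at least 0.5. The shifted windows of chromosome 8 reach -0.82 in the BRG1 knockout and the lower ones of chromosome 16 reach -0.63 in the BRM knockout.

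Over the 111 list tests camera passed 34, and with an estimated correlation 0 passed, with 14 at an unadjusted p under 0.05, while fry passed 55. In simulated data a list raised by 1 log2 unit passed with the estimated correlation in each comparison. Of 36 unchanged lists in that of BRM knockout and parental, 1 was called falsely by camera and 1 with the estimated correlation. The simulated genes were drawn independently of each other, so this does not show what the test recovers where members move together. In BRG1 knockout against parental the estimated correlation was 0.75 for epithelial and 0.93 for ribosomal protein genes.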

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

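The test for fibroblasts was chosen after the result was seen, and the tests of the differences between the knockouts and of the parental libraries were planned. Results were singled out where the 2 knockouts were called in opposite directions against parental cells and the direct comparison was called too. This was read over the 37 lists and for SMARCA4, SMARCA2, NFE2L2 and KEAP1. It gave the mesenchymal and secretory airway lists, KEAP1 and 1 count of genes. In the direct comparison alone camera passed 14 lists. Mesenchymal genes differed by a median of 3.47 (camera adjusted p = 1.5e-15; adjusted p = 0.0512 with an estimated correlation) and secretory airway genes by one of -7.11 (camera adjusted p = 9.5e-08; adjusted p = 0.318 with an estimated correlation). KEAP1 differed by 1.14 ± 0.13 (SE, n = 3 per group; edgeR adjusted p = 4.6e-05), and it rose by 0.53 ± 0.13 in the BRG1 knockout and fell by 0.61 ± 0.13 in the BRM knockout. KEAP1 lies near SMARCA4 on chromosome 19, and a local effect of the editing of SMARCA4 on it was not tested. In all, 954 genes were called in opposite directions in the knockouts and passed in the direct comparison (edgeR quasi-likelihood test). Opposite calls against the same controls all but fix such a pass beforehand, and they make it likely for the 2 lists and KEAP1 too. Independent lists would give 1480 genes called in opposite directions, and 2787 genes were called in the same direction.

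Of 22 mesenchymal genes, 17 rose and 1 fell in the BRG1 knockout, and 1 rose and 13 fell in the BRM knockout (camera adjusted p = 4.7e-07 and 2.9e-07; adjusted p = 0.231 and 0.433 with an estimated correlation). Of 15 secretory airway genes, 12 fell in the BRG1 knockout, and 7 rose and 1 fell in the BRM knockout (camera adjusted p = 5.9e-06 and 0.023; adjusted p = 0.446 and 0.787 with an estimated correlation). A parental library far from the other two, as the whole cause, is argued against: with each parental library left out in turn, the smallest median in the direction of the whole set, over both lists and both knockouts, was 1.32. Fibroblasts mixed into the BRG1 knockout libraries are argued against too, since COL1A2 reached at most 0.866% of COL3A1 in these libraries, at 0.48, 0.95 and 0.47 CPM, and fibroblasts make both. A biological difference between the losses of the 2 ATPases, which the groups name, stays open and untested, as does a difference between clones, since the labels do not say whether each knockout was a clone or a pool.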

How the results depend on the processing

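The GC content and length correction and the settings that leave out 2 libraries at once were chosen after the result was seen; the other settings were planned. Of 212 comparisons of the main results with other settings 198 stayed the same, as did 1796 of 1815 for named genes and 1297 of 1404 for lists. With 1 library left out these were 156 of 162, 1465 of 1485 and 952 of 972. A count was the same within a fixed fold range and the correlation within 0.052. A test or list was the same if its call was unchanged, whatever its size, or its sign where it was never called. Thus 3984 genes lower in the BRG1 knockout and 5029 without BRG1 knockout replicate 3 counted as the same. So did NRF2 target medians of 0.10 and -0.09 in that knockout. SMARCA4 in the BRM knockout, 0.13 without a call, was -0.38 after the GC content and length correction (edgeR adjusted p = 0.013), and the cause was not tested. SMARCA2 in the BRG1 knockout, -0.26 without a call, was -0.70 with both libraries that stand apart left out (edgeR adjusted p = 0.0086) and -0.62 to -0.14 with 1 library left out, and the cause was not tested. The correlation of the knockouts, 0.239, was 0.369 with no filter, 0.150 with the strict filter of 50 mean counts, 0.328 with both libraries that stand apart left out, 0.185 with BRG1 knockout 1 and 2 left out, and 0.213 to 0.319 with 1 library left out. A log2 threshold of 1 left 2490 genes higher and 2595 lower in the BRG1 knockout, 2328 and 1608 in the BRM knockout, 2194 and 3087 in the direct comparison and 1403 shared, by construction. With 1 library left out, genes higher in the BRM knockout numbered 2457 to 4033 and shared genes 1651 to 3455. Of 34 list calls by camera, 0 stayed with an estimated correlation. Over all 111 list tests, called by camera or not, 14 had an unadjusted p under 0.05 with the estimated correlation, and fry called 55.

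Replicate numbers gave no clear sign of pairing: deviations of same-numbered libraries correlated at -0.079 to 0.175, and of different-numbered ones at -0.154 to 0.118. The highest value was that of parental replicate 1 with BRG1 knockout replicate 1, and pairing is not excluded. With a replicate block, 3641 genes were higher and 3845 lower in the BRG1 knockout, 3622 and 2770 in the BRM knockout, and 3606 and 4196 in the direct comparison, and 10637 differed among the groups.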

Other observations

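The tests for parental cells in the BRG1 knockout libraries, for a wrong label and for GC content on the 2 named chromosome runs were chosen after the result was seen, and the other tests of chromosome windows and of sample splits were planned. The MHC class II list did not pass in either knockout or between them (camera adjusted p = 0.095 in the direct comparison), and its median against the parental mean was 2.07, 2.22 and 0.68 in the 3 BRG1 knockout libraries and 0.70 in parental replicate 1. In the BRG1 knockout 8 of 13 measured members rose, 1 fell and 4 did not pass (median 1.88; camera adjusted p = 0.24), with the invariant chain CD74 up by 2.58 ± 0.80 (SE, n = 3 per group; edgeR adjusted p = 0.026) and the protease CTSS at -4.46 ± 0.62. In the BRM knockout 10 of 13 members did not pass, CD74 fell by 3.33 ± 0.95 and CTSS rose by 1.55 ± 0.51, and adjusted over the list alone 0 were higher and 0 lower (median -0.18; camera adjusted p = 0.58). MHC class I genes had medians of -0.34 and -0.18 in the BRG1 and BRM knockouts (camera adjusted p = 0.58 and 0.57), with B2M, the light chain, up by 1.33 ± 0.21 and the peptide transporter TAP1 at -1.58 ± 0.26 in the BRG1 knockout. Immediate early genes rose in 12 of 23 and fell in 2 in the BRM knockout (median 0.67; camera adjusted p = 0.065), and FOS rose by 2.85 ± 0.90 with BRG1 loss and 2.90 ± 0.90 with BRM loss. Their median with BRG1 loss was 0.53 (camera adjusted p = 0.63). In MAPK output, the ligands AREG and EREG fell (log2 -6.24 ± 0.75 and -4.86 ± 0.57) and the feedback phosphatase DUSP6 fell by 2.50 ± 0.24 in the BRG1 knockout, whereas the ligand HBEGF rose by 3.65 ± 0.29. Among squamous and basal genes, with medians of -1.36 and 1.12 (camera adjusted p = 0.081 and 0.18), the transcription factor TP63 fell by 4.73 ± 0.52 with BRG1 loss and rose by 2.43 ± 0.45 with BRM loss, and the keratin KRT17 rose by 6.74 ± 1.02 with BRG1 loss. Interferon genes had a median of 0.49 in the BRM knockout (camera adjusted p = 0.076), and MX1 rose there by 3.56 ± 0.53.

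Metabolic lists did not pass in either knockout. Fatty acid synthesis had medians of -0.31 and 0.06 in the BRG1 and BRM knockouts (camera adjusted p = 0.12 and 0.52; the mean was -0.38 in the latter, of opposite sign), and FASN, the fatty acid synthase, fell by 1.68 ± 0.29 with BRG1 loss. Cholesterol synthesis had -0.42 and -0.06 (camera adjusted p = 0.5 and 0.86; mean 0.02 in the latter, of opposite sign). Glycolysis and hypoxia genes had 0.16 and 0.25 (camera adjusted p = 0.5 and 0.92; mean -0.05 in the latter), and the glucose transporter SLC2A3 rose by 1.29 ± 0.25 and fell by 1.69 ± 0.26. Oxidative phosphorylation genes lay at 0.05 and -0.09 (camera adjusted p = 0.57 and 0.41) and mitochondrial transcripts at -0.01 and -0.02 (camera adjusted p = 0.79 and 0.86). Drug metabolism genes lay at -0.29 and 0.28 (camera adjusted p = 0.5 and 0.41), with AHRR, the repressor of the aryl hydrocarbon receptor, up by 2.95 ± 0.24 and the aldehyde dehydrogenase ALDH1A3 at -3.61 ± 0.78 with BRG1 loss. Inflammatory cytokines lay at -0.28 and -0.12 (camera adjusted p = 0.68 and 0.18; mean -0.48 in the latter). Of 27 measured, 6 rose and 7 fell with BRG1 loss and 2 rose and 10 fell with BRM loss, the latter 5 and 11 adjusted over the list alone, and the cyclooxygenase PTGS2 rose by 3.23 ± 0.68 and 2.50 ± 0.66. Adhesion molecules lay at 0.66 and 0.43 (camera adjusted p = 0.62 and 0.86), with P-cadherin, CDH3, at -3.99 ± 0.64 and the integrin ITGB3 up by 3.54 ± 0.72 with BRG1 loss. Polycomb genes lay at -0.07 and -0.03 (camera adjusted p = 0.86 and 0.46), and the methyltransferase EZH2 fell (log2 -1.31 ± 0.20 and -1.91 ± 0.20). Wnt targets lay at -0.15 and 0.08, with means of 0.22 and -0.91 of opposite sign (camera adjusted p = 0.79 and 0.22), and AXIN2, a feedback inhibitor of the pathway, rose by 1.21 ± 0.26 and fell by 1.51 ± 0.27. Neuroendocrine genes lay at 0.61 and 0.44 (mean -0.51 in the latter, of opposite sign; camera adjusted p = 0.86 and 0.96) and HOX genes at -1.50 and -0.96 (camera adjusted p = 0.68 and 0.58). Blood cell markers lay at -0.24 and -0.71 (camera adjusted p = 0.29 and 0.28) and endothelial markers at -0.75 and -1.46, the latter with a test statistic above 0 (camera adjusted p = 0.46 and 0.86).

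The median of all 30 epithelial genes against the parental mean was -2.97 and -2.94 on the log2 scale in BRG1 knockout replicates 1 and 2 and -6.14 in replicate 3. The 12 members picked for lying at or below 1% of the parental level in replicate 3, with at least 10 CPM in parental cells, had medians of 9.38%, 9.41% and 0.073% in replicates 1, 2 and 3, with a range from 0.55% to 32.21% in the first 2, while LSR, for example, stood at 47.81%, 51.55% and 34.73%. Parental cells mixed into replicates 1 and 2 are argued against as the whole cause, since they would bring every gene that is near 0 in replicate 3 at 1 common share. Of 89 such genes, the 12 epithelial members included, 25.8% had an upper 95% counting limit below 1/3 of the median share of these 12 in both libraries. A wrong label on replicate 3 is argued against by SMARCA4, at 11.1% of the lowest parental or BRM knockout library, and no biological explanation was tested.

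Windows of neighbouring genes shifted together in both knockouts. Over all shifted windows, 50% kept their distance after the correction for GC content and length, so that such a trend and a local change cannot be told apart for them. On the runs of chromosomes 8 and 16 that trend is argued against, with a smallest distance of 0.54 after the correction. A difference in copy number predicted that the far quartile of genes in shifted windows moves too, and it moved by 103.5% of the median shift. These windows were picked for a shifted median, and any cause that moves a whole window would give the same. The value therefore does not tell copy number from a GC content trend or a local change. DNA was not measured, and a difference in copy number stays open.

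Other splits of the samples were tested for the counts of genes called. The 100 splits of the 9 samples were the real one and others drawn at random. Of these, 1, the real one, called as many as 11224 genes that differ among the 3 groups, and the highest other called 3441. Among the 10 splits of 6 samples, 1 called as many as 7033 for BRG1 knockout against parental, 1 as many as 8389 for BRM knockout against parental and 1 as many as 7242 for the direct comparison, the real one each time, and 10 splits are too few for a share under 0.05. Splits that mix groups this far apart add the group difference to the spread within their parts. Low counts in such splits were therefore likely beforehand and say little about the real groups.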
